A study of Mus musculus with 24 samples.

How the data were processed

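RNA of neocortex, cerebellum and hippocampus was extracted with Trizol, made into libraries with a stranded TruSeq kit for messenger RNA and sequenced on a NovaSeq instrument, per the labels' protocols. The authors deposited 1 table of TPM values (transcript abundances scaled to the same total in each library) with 47643 gene symbols and 24 libraries. The genome build was mm10, per the submitters' processing notes; the aligner, the counting tool, the annotation and any filter are not given in the sources used here. TPM divides by transcript length and by the total of the library, so a gene that takes a larger share lowers the values of all others, and the number of reads is lost. The low values still show steps, which give the relative depth: among genes under 1 TPM, 11.1% to 15.3% of the ratios to control neocortex replicate 14 fell within 0.5% of their most frequent value, which gave the relative TPM value of 1 read, 0.978 to 1.27 across libraries. The 10 genes with the highest values held 18.9% to 26.1% of the TPM of a library. Whether values at 0 reflect a failed estimate is not known; 23222 symbols were at 0 in all libraries.

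Groups came from the titles: 3 regions, each with LLC replicates 1 to 4 and control replicates 14 to 17. The labels call the libraries biological replicates but do not say whether the 3 libraries of a number come from the same animal. No pair of libraries was identical. Symbols were matched to GENCODE M21 on mm10 for coordinates, GC content and length, and 94.6% of them matched exactly 1 gene.

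Each region was tested with limma 3.58.1 (lmFit, and eBayes with a trend) in R 4.3.3 on log2(TPM + 1), over genes with a mean TPM of at least 1 in its 8 libraries, with two-sided tests and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates those of low genes. The region average used the mean of log2(TPM + 1) over the 3 regions per replicate number, and differences between regions were contrasts in 1 fit of all 24 libraries over genes passing the filter in both regions. In total 44 gene lists were fixed before the data were examined, and those with at least 5 tested members were tested with camera at a preset correlation of 0.01, 126 tests over the 3 regions, adjusted together. Of these, 49 passed, 31 upward and 18 downward, and for all 49 the median, the mean and the test had the same sign. With the correlation estimated from the data 0 passed (15 at an unadjusted p under 0.05), and fry, which asks only whether the members move one way, called 23. Some genes sit on several lists, such as Lcn2, Icam1 and Cebpd, so the lists are not independent.

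Named genes followed a rule fixed before the data were examined: per comparison the 10 rising and 10 falling genes with the largest change among those that passed with all LLC libraries on one side of all controls, and the passing members of the lists, at most 4 of each by p. Where fewer than 10 passed, the 5 rising and 5 falling genes with the smallest p are given as not passing. Predicted genes named only by an identifier and pseudogenes were left out. A few genes that met the rule and 1 marker gene of the regions are not reported here and were left out of the search for libraries that lie apart. Alternatives were a pseudocount of 0.1, filters at a mean of 5 TPM or none, median-ratio and quantile scaling, robust eBayes, library weights, all 24 libraries in 1 fit, the description or title number as a block, and leaving out each replicate. Removal of each library's trend with GC content and length (splines with 4 degrees of freedom) and weights per region were chosen after seeing the data.

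The fits were tested on simulated data with genes changed by known folds. Of genes changed 1.5-fold, 92.3% were recovered in neocortex, 68.7% in cerebellum and 77.3% in hippocampus, and of genes changed 2-fold 98.5%, 94.0% and 95.4%. The share of called genes that had not been changed was 7.77%, 4.92% and 4.81%, and 4.78% for the region average. For differences between regions it was 15.2% for cerebellum against neocortex, 14.4% for hippocampus against cerebellum and 6.59% for hippocampus against neocortex, and with weights per region 15.4%, 5.85% and 12.3%. These and the neocortex value lie above the set rate of 5%, some by few genes (12 of 182 called for hippocampus against neocortex without weights). Each setting was simulated once, with noise drawn independently for every gene and library. Correlated genes, shared animals and outlying libraries were not part of the simulation, so its shares may not hold for the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.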

Results

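Gene expression was profiled by bulk RNA sequencing in the neocortex, cerebellum and hippocampus of male C57BL/6J mice aged 4 months, after injection of LLC cells that grew for up to about 3 weeks or after a mock injection. LLC usually stands for Lewis lung carcinoma, a mouse tumour cell line, but the labels do not spell it out and the series title speaks of melanoma. The series concerns tumour-induced wasting and how it affects different organs, and these libraries address the brain. Each region had 4 LLC and 4 control libraries, 24 in all, which the labels call biological replicates. LLC libraries carry the numbers 1 to 4 and control libraries 14 to 17 in each region. The values are TPM, transcript abundances scaled to the same total in each library, which give no number of reads, so the absolute depth is unknown. Between 14368 and 14847 genes reached 1 TPM in each library, and the TPM value of a single read, relative to control neocortex replicate 14, was estimated at 0.978 to 1.27. No 2 of the 276 library pairs held identical values.

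The libraries followed their region labels. Gabra6, a GABA receptor subunit of cerebellar granule cells, lay between 455 and 986 TPM in the 8 cerebellar libraries and at most at 0.403 TPM in the others. Prox1, a transcription factor of dentate granule cells, ranged from 30.9 to 52.7 TPM in hippocampus, 18.4 to 35.3 TPM in cerebellum and 6.91 to 8.77 TPM in neocortex. Cerebellar LLC replicate 1 stood apart in make-up: its mean log2 difference from controls was -0.84 over the cerebellum markers, against -0.03, -0.07 and 0.02 in LLC replicates 2 to 4 and -0.12 to 0.08 in controls, and 0.40 over the myelin genes, against -0.51, -0.47 and -0.02. Its TPM value of 1 read was 1.03, against 1.19 to 1.27 in the other cerebellar libraries.

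The neocortex of LLC mice held more transcripts of red blood cells, neutrophils, blood vessels and the acute-phase response than control neocortex, and fewer of cholesterol synthesis, myelin and several heat shock genes. Of the calls for whole gene lists behind this summary, 0 passed with an estimated correlation in any of the 3 regions. The myelin list also passed with fry in no region (lowest fry adjusted p = 0.0627). The haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt together made up 11265 ± 5368 TPM in LLC and 1327 ± 172 TPM in control neocortex (SD, n = 4 each). Lcn2, which encodes the siderophore-binding acute-phase protein lipocalin 2, rose from 0.186 ± 0.105 to 6.61 ± 1.54 TPM. Gkn3, a gastrokine gene expressed in brain endothelium, fell from 9.82 ± 1.47 to 4.23 ± 0.916 TPM. Of 14485 genes tested with limma, 1237 changed, 809 upward and 428 downward.

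Blood cell transcripts had the largest increases. Log2 fold changes were 3.32 ± 0.40 (SE) for Hbb-bt (chromosome 7, 103812524 to 103813996), 2.96 for Hbb-bs, 2.86 for Hba-a1 and 2.68 for Hba-a2. Reads can be shared between the 2 alpha and between the 2 beta globin copies, so their single values are uncertain. Alas2, the erythroid enzyme that starts haem synthesis (chromosome X, 150547375 to 150570638), rose from 4.74 ± 0.582 to 65.2 ± 31.5 TPM. Of 7 tested erythrocyte genes 6 rose, and 7 did when adjusted over the list alone (camera adjusted p = 1.20e-07, and adjusted p = 0.399 with an estimated correlation). S100a9 (chromosome 3, 90692632 to 90695721) and S100a8, the subunits of calprotectin in neutrophils, rose from 3.42 ± 1.43 to 64.0 ± 45.3 TPM and from 2.31 ± 0.337 to 33.1 ± 22.4 TPM. The neutrophil genes Retnlg and Chil3 rose by log2 fold changes of 2.56 ± 0.29 and 2.51 ± 0.18. Among 9 tested neutrophil genes 6 rose, and all 9 did when adjusted over the list alone (camera adjusted p = 9.19e-08, and adjusted p = 0.399 with an estimated correlation). The summed haemoglobin genes stood at 11688, 14735, 15090 and 3545 TPM in LLC replicates 1 to 4, and a sum of 14 neutrophil genes at 50.5, 181, 68.1 and 215 TPM.

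Acute-phase genes, targets of cytokine signalling through STAT3, rose as a group. Of 16 tested members 11 rose and 0 fell, 13 rose when adjusted over the list alone, and the median log2 fold change was 0.54 (camera adjusted p = 4.21e-10, and adjusted p = 0.367 with an estimated correlation). Lcn2 (chromosome 2, 32384633 to 32388252) had a log2 fold change of 2.67 ± 0.13 (limma adjusted p = 1.16e-05). Lrg1, a leucine-rich secreted glycoprotein (chromosome 17, 56119678 to 56122001), rose from 2.04 ± 0.198 to 12.4 ± 1.43 TPM, with a log2 fold change of 2.13 ± 0.09 (limma adjusted p = 2.76e-06). Ch25h, a cholesterol 25-hydroxylase, and Icam1, a leukocyte adhesion molecule, rose by 1.90 ± 0.23 and 1.28 ± 0.16. Glucocorticoid-responsive genes were higher, with 8 of 21 members passing and 15 when adjusted over the list alone (camera adjusted p = 2.73e-06, and adjusted p = 0.550 with an estimated correlation). Sult1a1, Cebpd, Gjb6 and Mt1 were among the 8, with log2 fold changes of 1.48, 1.25, 0.71 and 0.53. The mean log2 difference of this list from controls was 0.98, 0.85, 0.85 and 0.00 in LLC replicates 1 to 4. With fry it passed in no region (lowest adjusted p = 0.0591). Of 21 reactive astrocyte genes 8 rose, with 11 up and 1 down when adjusted over the list alone, Vim, Srgn and Cp among them (camera adjusted p = 1.01e-04, and adjusted p = 0.367 with an estimated correlation). In the complement list 3 of 9 tested members rose, C5ar1 and C4b among them, and 5 when adjusted over the list alone (camera adjusted p = 0.0165, and adjusted p = 0.367 with an estimated correlation). That complement call was lost without LLC replicate 4 (adjusted p = 0.126).

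Vascular genes rose across cell layers of the vessel wall. Among 18 endothelial genes 15 rose and 1 fell, 17 and 1 when adjusted over the list alone, with a median log2 fold change of 0.61 (camera adjusted p = 3.90e-12, and adjusted p = 0.367 with an estimated correlation). Vwf, the von Willebrand clotting factor (chromosome 6, 125546774 to 125686679), rose from 4.24 ± 0.240 to 31.3 ± 11.3 TPM, and Ly6a, Flt1 and Pecam1 rose by 1.42 ± 0.16, 0.85 ± 0.11 and 0.94 ± 0.12. The 1 member that fell was Itm2a, a membrane protein of brain endothelium (-0.35 ± 0.06), which is named here after its value was seen. Mural genes rose in 5 of 11 cases, 8 when adjusted over the list alone, including Abcc9 (1.02 ± 0.17) and Notch3 (camera adjusted p = 1.23e-04, and adjusted p = 0.415 with an estimated correlation). Basement membrane genes rose in 8 of 13 cases, 9 when adjusted over the list alone, including Fn1 (1.01 ± 0.12), Col4a1 and Col4a2 (camera adjusted p = 1.18e-06, and adjusted p = 0.399 with an estimated correlation). Of 17 hypoxia-responsive genes 7 rose, 8 when adjusted over the list alone, including Adm (1.76 ± 0.36), Angptl4, Slc2a1 and Vegfa (camera adjusted p = 6.62e-04, and adjusted p = 0.499 with an estimated correlation). LLC replicates 1 to 4 had mean log2 differences from controls of 0.67, 0.58, 0.53 and 0.11 over this list. With fry it passed in no region (lowest adjusted p = 0.0593).

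Cholesterol synthesis genes fell together. Of 19 members 16 fell, 17 when adjusted over the list alone, and the median log2 fold change was -0.44 (camera adjusted p = 2.19e-14, and adjusted p = 0.370 with an estimated correlation). Cyp51, Hmgcs1 and Sqle had log2 fold changes of -0.71 ± 0.09, -0.71 ± 0.12 and -0.55 ± 0.09. Heat shock genes fell in 6 of 13 cases, 8 when adjusted over the list alone, Cryab, Hsph1 and Hspd1 among them (camera adjusted p = 0.00104, and adjusted p = 0.430 with an estimated correlation). Of 15 myelin genes 6 fell and 1 rose, 11 and 2 when adjusted over the list alone: Mag fell by 0.38 on the log2 scale, and Mal rose by 0.43 (camera adjusted p = 3.72e-04, and adjusted p = 0.424 with an estimated correlation). Pan-neuronal genes fell in 6 of 13 cases, 8 when adjusted over the list alone, including Tubb3 (-0.46 ± 0.09) and the neurofilament genes Nefl and Nefm (camera adjusted p = 1.91e-04, and adjusted p = 0.424 with an estimated correlation). The pan-neuronal list passed with fry in no region (lowest fry adjusted p = 0.0591).

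Shifts were also called in 5 other lists of neocortex. The 20 immediate early genes had a median log2 fold change of -0.37 with 1 falling member, Arc (-1.12 ± 0.29), and 7 when adjusted over the list alone (camera adjusted p = 3.07e-05, and adjusted p = 0.560 with an estimated correlation). Relative to controls, the mean of the list was -0.65, -0.08, -0.59 and -0.48 in LLC replicates 1 to 4 on the log2 scale, with control replicate 14 at -0.40. Microglial genes had a median of -0.27 with 0 of 15 members passing either way (camera adjusted p = 0.00136, and adjusted p = 0.656 with an estimated correlation). In LLC replicates 1 to 4 the mean log2 difference from controls was -0.35, -0.25, -0.46 and 0.12, with replicate 4 above all controls. Genes of the unfolded protein response had a median of -0.12 and 1 falling member, Atf4, also when adjusted over the list alone (camera adjusted p = 0.00845, and adjusted p = 0.560 with an estimated correlation). Nuclear genes of the respiratory chain had a median of -0.07, and Cox5a, Cycs and Ndufa1 fell out of 20, also when adjusted over the list alone (camera adjusted p = 0.0105, and adjusted p = 0.494 with an estimated correlation). GABAergic genes had a median of -0.11 with 1 of 15 falling, Cck, and 2 up and 4 down when adjusted over the list alone (camera adjusted p = 0.0349, and adjusted p = 0.430 with an estimated correlation). The respiratory chain call was lost without LLC replicate 4 (adjusted p = 0.0772), and the GABAergic call without LLC replicate 1 (0.0505), LLC replicate 3 (0.0612) or control replicate 15 (0.0523). The immediate early, microglial, unfolded protein response and respiratory chain lists passed with fry in no region (lowest fry adjusted p = 0.217, 0.318, 0.217 and 0.0934).

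Beside Gkn3, the largest decreases were those of Klk6, Myoc, Dio2, Hes5, Tst, Klf10, Tnnc1, Ugt8a and Acat3. Klk6, an oligodendrocyte protease, fell from 8.37 ± 1.30 to 3.58 ± 2.01 TPM, Dio2, the enzyme that activates thyroid hormone, from 46.7 ± 5.42 to 24.5 ± 8.16 TPM, and Hes5, a Notch target, from 26.9 ± 2.10 to 14.3 ± 4.78 TPM. Log2 fold changes of the other 6 lay between -0.95 for Myoc and -0.77 for Acat3. Among the 4 LLC libraries, Klk6, Myoc, Hes5 and Tst were highest in replicate 4, at 6.59, 25.9, 21.5 and 43.5 TPM.

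At an unadjusted p under 0.05 there were 4320 neocortex genes against 724 by chance, and 2469 genes had all 4 LLC libraries on one side of all 4 controls against 414 by chance. With median-ratio scaling of the libraries the split was 707 up and 575 down, and with quantile normalization 613 and 517. The count rested on single libraries: it was 187, 207, 496 and 3834 without LLC replicates 1 to 4, and 565, 226, 220 and 327 without control replicates 14 to 17. Of the 20 genes with the largest changes, 13 kept their call in all 8 of these fits: Lcn2, Vwf, Retnlg, S100a8, S100a9, Alas2, the 4 haemoglobin genes, Klf10, Gkn3 and Tnnc1.

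In the cerebellum of LLC mice, blood cell and acute-phase transcripts were again higher, while Lnpep, Plcxd3, Ptar1 and other genes, and cholesterol synthesis, were lower. The 4 haemoglobin genes together made up 12204 ± 5338 TPM in LLC and 1430 ± 184 TPM in control cerebellum (SD, n = 4 each). Lcn2 rose from 0.290 ± 0.153 to 6.91 ± 1.60 TPM and Lrg1 from 0.916 ± 0.173 to 10.3 ± 1.62 TPM. Lnpep, a membrane aminopeptidase (chromosome 17, 17521410 to 17625050), fell from 41.9 ± 12.9 to 9.41 ± 5.68 TPM. Of 14624 genes tested with limma, 366 changed, 180 upward and 186 downward.

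All 4 haemoglobin genes rose, by log2 fold changes of 2.80 to 3.28 ± 0.36, with the same uncertainty between copies, and Alas2 rose by 3.26 ± 0.43. Erythrocyte genes rose in 7 of 8 cases, 8 when adjusted over the list alone (camera adjusted p = 6.23e-12, and adjusted p = 0.367 with an estimated correlation). S100a8, S100a9, Retnlg and Chil3 rose by 2.91 ± 0.41, 2.94 ± 0.48, 2.06 ± 0.27 and 2.10 ± 0.16, 4 of 8 neutrophil genes, with 6 when adjusted over the list alone (camera adjusted p = 6.51e-09, and adjusted p = 0.367 with an estimated correlation). Summed haemoglobin stood at 14770, 14341, 15477 and 4228 TPM in LLC replicates 1 to 4, and the neutrophil sum at 47.9, 114, 53.9 and 162 TPM.

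Acute-phase genes rose in 9 of 19 cases, 10 up and 1 down when adjusted over the list alone (camera adjusted p = 2.28e-11, and adjusted p = 0.367 with an estimated correlation). Beside Lcn2 and Lrg1, which had limma adjusted p = 1.71e-04 and 2.69e-05, Ch25h, Icam1, Cebpd and Bcl3 rose by 1.75 ± 0.21, 1.16 ± 0.21, 1.25 ± 0.26 and 0.75 ± 0.12. Gpx3, a secreted glutathione peroxidase, rose from 10.6 ± 3.25 to 58.9 ± 29.3 TPM. Glucocorticoid-responsive genes passed in 3 of 21 cases, Cdkn1a, Cebpd and Map3k6, and in 15 when adjusted over the list alone (camera adjusted p = 1.18e-09, and adjusted p = 0.424 with an estimated correlation). Their mean log2 difference from controls was 1.11, 0.96, 0.95 and 0.02 in LLC replicates 1 to 4. Reactive astrocyte genes rose in 3 of 24 cases, Lcn2, Fbln5 and Osmr, with 9 up and 1 down when adjusted over the list alone (camera adjusted p = 3.20e-04, and adjusted p = 0.415 with an estimated correlation). Hypoxia-responsive genes rose in 2 of 18 cases, Vegfa and Ankrd37, and in 9 when adjusted over the list alone (camera adjusted p = 2.28e-06, and adjusted p = 0.399 with an estimated correlation). LLC replicates 1 to 4 had mean log2 differences from controls of 0.67, 0.50, 0.50 and 0.09 over this list.

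Endothelial genes rose in 4 of 18 cases and fell in 1, with 10 and 1 when adjusted over the list alone (camera adjusted p = 2.37e-07, and adjusted p = 0.424 with an estimated correlation). Vwf rose from 4.97 ± 0.653 to 24.6 ± 8.02 TPM, Ly6a by 1.10 ± 0.17 and Ly6c1 by 1.04 ± 0.18, and Itm2a fell by 0.64 on the log2 scale. Basement membrane genes rose in 4 of 13 cases, Sparc, Fn1, Col4a1 and Col4a2, with 6 up and 1 down when adjusted over the list alone (camera adjusted p = 0.00261, and adjusted p = 0.367 with an estimated correlation). Mural genes had a median log2 fold change of 0.05 with 1 riser, Abcc9, and 3 when adjusted over the list alone (camera adjusted p = 0.0322, and adjusted p = 0.577 with an estimated correlation). The mural call was lost without LLC replicate 1 (adjusted p = 0.355, median -0.01), without control replicate 14 (0.174, median -0.02) and with median-ratio scaling (0.0697). Complement genes had a median of 0.23 with 0 of 9 passing and 1 when adjusted over the list alone (camera adjusted p = 0.00259, and adjusted p = 0.494 with an estimated correlation), and inflammatory cytokine genes a median of 0.12 with 1 of 10 rising, Icam1, and 4 when adjusted over the list alone (camera adjusted p = 0.0201, and adjusted p = 0.415 with an estimated correlation). Both calls were lost without LLC replicate 1 (adjusted p = 0.0848 and 0.0821). The cytokine list passed with fry in no region (lowest fry adjusted p = 0.0627).

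Cholesterol synthesis genes fell in 6 of 18 cases, 9 when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 1.81e-05, and adjusted p = 0.494 with an estimated correlation). Sc5d, Stard4 and Idi1 had log2 fold changes of -0.46 ± 0.08, -0.53 ± 0.10 and -0.62 ± 0.13. Heat shock genes fell in 3 of 13 cases, Hspa4l, Hsph1 and Hspd1, and in 8 when adjusted over the list alone (camera adjusted p = 5.60e-04, and adjusted p = 0.367 with an estimated correlation). Ribosomal protein genes had a median of 0.13 with 0 of 28 passing either way (camera adjusted p = 2.00e-06, and adjusted p = 0.622 with an estimated correlation). That median was 0.02 once the trends with GC content and length were removed, and the mean log2 difference of the list from controls was 0.32, 0.10, 0.06 and 0.03 in LLC replicates 1 to 4. The ribosomal list passed with fry in no region (lowest fry adjusted p = 0.175). The largest decreases were Lnpep, Plcxd3, Ptar1, Lmbrd2, Arfgef3, Lcor, Fabp7, Klhl28, Fzd3 and Dgkh, with log2 fold changes of -2.25 to -1.47. Fabp7, a fatty acid-binding protein of radial glia and astrocytes, had a log2 fold change of -1.62 ± 0.32, and the frizzled receptor gene Fzd3 fell from 15.2 ± 2.88 to 4.85 ± 1.84 TPM. The 186 falling genes had a median transcript length of 4764 bases and a median GC content of 41.1%, against 3346 bases and 49.8% among the genes tested.

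At an unadjusted p under 0.05 there were 3563 cerebellar genes against 731 by chance, and 2442 genes separated the groups completely against 418 by chance. The count was 1288, 17, 48 and 1570 without LLC replicates 1 to 4, and 27, 9, 6 and 45 without control replicates 14 to 17. Of the 20 genes with the largest changes, Lrg1, Lcn2 and Hbb-bt kept their call in all 8 of these fits. With median-ratio scaling 435 genes rose and 307 fell, and with quantile normalization 472 and 353. Once each library's trend with GC content and length was removed, a setting chosen after seeing the data, 88 rose and 66 fell.

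In the hippocampus of LLC mice the same groups of blood, vascular and acute-phase transcripts were higher and cholesterol synthesis was lower, and the vasopressin gene Avp was higher as well. The 4 haemoglobin genes made up 6926 ± 3209 TPM in LLC and 948 ± 230 TPM in control hippocampus (SD, n = 4 each). Avp (chromosome 2, 130580620 to 130582554) rose from 2.30 ± 2.40 to 16.4 ± 8.48 TPM, with a log2 fold change of 2.46 ± 0.48 (limma adjusted p = 0.0298). Control replicate 17 held 5.88 TPM of it, and in neocortex it ranged from 2.06 to 58.8 TPM over the LLC libraries and from 4.07 to 27.4 TPM over the controls. Zbed6 (chromosome 1, 133655879 to 133660885) fell from 5.43 ± 1.18 to 1.18 ± 0.167 TPM; it lies within an intron of Zc3h11a, so its reads cannot be fully told apart from that gene's. Of 14650 genes tested with limma, 529 changed, 378 upward and 151 downward.

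Haemoglobin genes rose by log2 fold changes of 2.57 to 3.01 ± 0.34, uncertain between copies as before, and Alas2 by 3.14 ± 0.40. Erythrocyte genes rose in 5 of 6 cases, 6 when adjusted over the list alone (camera adjusted p = 1.70e-08, and adjusted p = 0.367 with an estimated correlation). S100a9, S100a8, Retnlg and Chil3 rose by 3.45 ± 0.55, 2.97 ± 0.40, 2.36 ± 0.27 and 1.67 ± 0.21, 4 of 7 neutrophil genes, with 5 when adjusted over the list alone (camera adjusted p = 1.05e-06, and adjusted p = 0.399 with an estimated correlation). Summed haemoglobin stood at 7057, 7701, 10338 and 2609 TPM in LLC replicates 1 to 4, and the neutrophil sum at 32.1, 88.3, 46.3 and 129 TPM.

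Acute-phase genes rose in 6 of 16 cases, 12 when adjusted over the list alone, including Lcn2 (2.02 ± 0.14), Lrg1 (1.80 ± 0.14) and Icam1 (1.00 ± 0.13) (camera adjusted p = 1.50e-08, and adjusted p = 0.367 with an estimated correlation). Glucocorticoid-responsive genes rose in 7 of 21 cases, 13 when adjusted over the list alone, including Sult1a1 (1.35 ± 0.29), Arrdc2 (1.00 ± 0.17), Cebpd and Mt1 (camera adjusted p = 7.22e-09, and adjusted p = 0.424 with an estimated correlation). The mean log2 difference of that list from controls was 0.77, 0.84, 0.80 and 0.13 in LLC replicates 1 to 4. Endothelial genes rose in 11 of 18 cases and fell in 1, with 16 and 1 when adjusted over the list alone (camera adjusted p = 3.35e-12, and adjusted p = 0.367 with an estimated correlation). Vwf rose from 2.54 ± 0.332 to 15.7 ± 5.19 TPM, and Ly6a, Pecam1 and Flt1 rose by 1.24 ± 0.15, 0.82 ± 0.09 and 0.79 ± 0.11; the member that fell was Itm2a (-0.48 ± 0.07), named after its value was seen. Mural genes rose in 3 of 11 cases, Kcnj8, Vtn and Abcc9, also when adjusted over the list alone (camera adjusted p = 3.12e-04, and adjusted p = 0.424 with an estimated correlation). Basement membrane genes rose in 3 of 13 cases, Sparc, Col4a1 and Fn1, and in 4 when adjusted over the list alone (camera adjusted p = 0.00251, and adjusted p = 0.502 with an estimated correlation). The mean log2 difference of that list from controls was 0.18, 0.57, 0.19 and 0.22 in LLC replicates 1 to 4, and LLC replicate 2 also had 1.95 over the choroid plexus genes, which ranged from -1.41 to 1.95 over the hippocampal libraries.

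Hypoxia-responsive genes rose in 2 of 18 cases, Slc2a1 and Vegfa, and in 11 when adjusted over the list alone (camera adjusted p = 3.18e-04, and adjusted p = 0.494 with an estimated correlation). LLC replicates 1 to 4 had mean log2 differences from controls of 0.54, 0.58, 0.51 and 0.10 over this list. Reactive astrocyte genes rose in 6 of 22 cases, 8 when adjusted over the list alone, including Vim (0.80 ± 0.09) and Fbln5 (camera adjusted p = 0.00242, and adjusted p = 0.424 with an estimated correlation). Cholesterol synthesis genes fell in 12 of 18 cases, 17 when adjusted over the list alone, with a median log2 fold change of -0.53 (camera adjusted p = 3.89e-15, and adjusted p = 0.399 with an estimated correlation). Msmo1, Hmgcs1, Cyp51 and Nsdhl had log2 fold changes of -0.86 ± 0.17, -0.78 ± 0.12, -0.64 ± 0.11 and -0.55 ± 0.09. Heat shock genes fell in 3 of 13 cases, Hspa4l, Hspd1 and Hsp90aa1, and 1 rose, Hspa1b, with 6 and 1 when adjusted over the list alone (camera adjusted p = 0.00108, and adjusted p = 0.367 with an estimated correlation). Hes5 fell from 19.8 ± 2.53 to 8.70 ± 2.92 TPM, Cort, the gene of the inhibitory neuropeptide cortistatin, from 26.6 ± 2.71 to 15.1 ± 4.15 TPM, and Kcna3, a voltage-gated potassium channel, from 2.19 ± 0.329 to 0.854 ± 0.195 TPM.

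Neuronal lists shifted by little. Pan-neuronal genes had a median of -0.15, with Stmn2 and Tubb3 falling and Rbfox3 rising out of 13, and 6 down and 1 up when adjusted over the list alone (camera adjusted p = 1.31e-04, and adjusted p = 0.415 with an estimated correlation). GABAergic genes had a median of -0.17, and Npy and Cck fell out of 15, 5 when adjusted over the list alone (camera adjusted p = 0.00160, and adjusted p = 0.367 with an estimated correlation). Microglial genes had a median of -0.23 with 0 of 15 passing and 2 falling when adjusted over the list alone (camera adjusted p = 5.90e-04, and adjusted p = 0.652 with an estimated correlation). In LLC replicates 1 to 4 the mean log2 difference from controls was -0.38, -0.23, -0.51 and 0.15, with replicate 4 above all controls. Genes of the unfolded protein response had a median of -0.09 with 0 of 16 passing either way (camera adjusted p = 0.0228, and adjusted p = 0.700 with an estimated correlation). Nuclear respiratory chain genes had a median of -0.04, with Cycs and Cox5a falling out of 20, also when adjusted over the list alone (camera adjusted p = 0.0300, and adjusted p = 0.700 with an estimated correlation). The unfolded protein response call was lost without LLC replicate 3 (adjusted p = 0.0836) or control replicate 17 (0.170), and the respiratory chain call without LLC replicate 4 (0.270) or control replicates 14 (0.0901) or 15 (0.110).

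At an unadjusted p under 0.05 there were 3259 hippocampal genes against 733 by chance, and 2016 genes separated the groups completely against 419 by chance. With median-ratio scaling the split was 320 up and 212 down, and with quantile normalization 322 and 235. The count was 104, 83, 153 and 1667 without LLC replicates 1 to 4, and 59, 57, 90 and 103 without control replicates 14 to 17. Of the 20 genes with the largest changes, Vwf, Zbed6, Alas2, Hbb-bs, Hbb-bt, Hba-a1, Retnlg and S100a8 kept their call in all 8 of these fits.

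**Figure D1:**
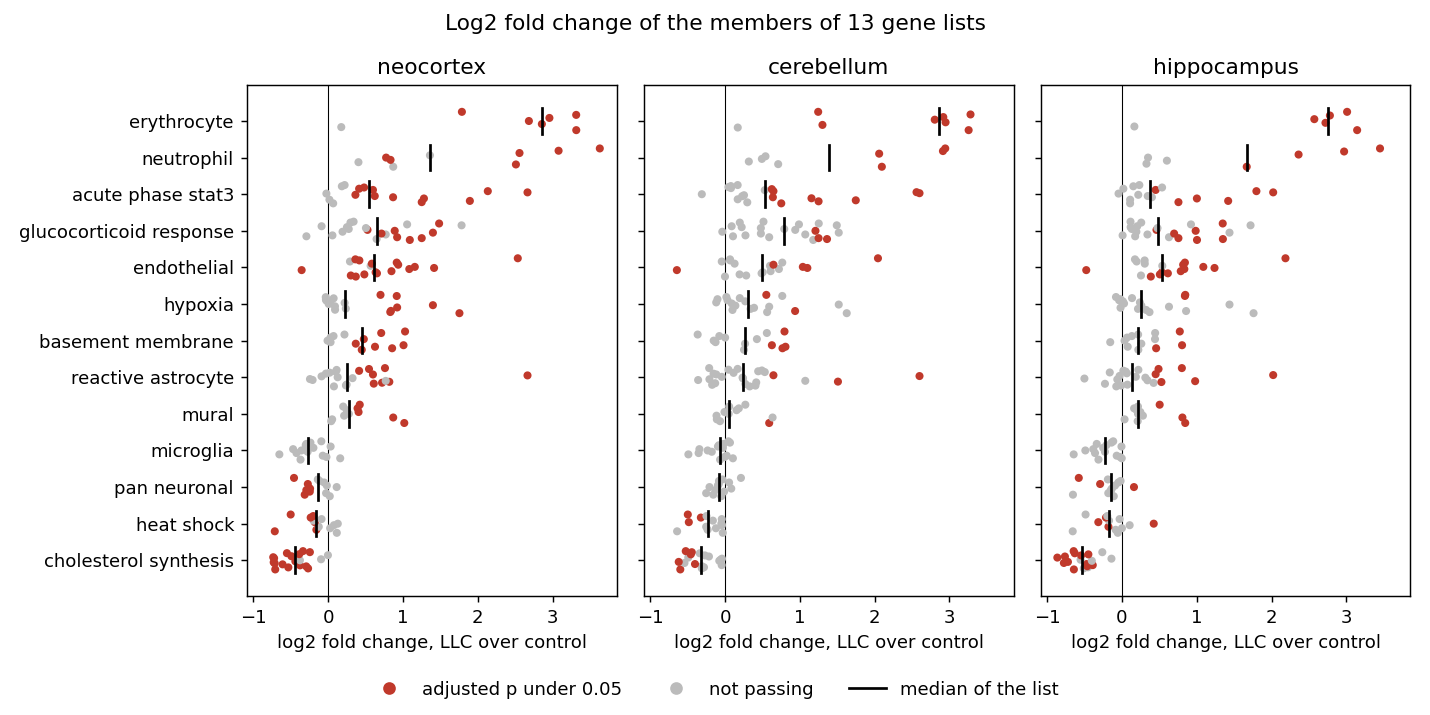
Log2 fold change (LLC over control, horizontal axis) of every tested member of 13 gene lists in neocortex, cerebellum and hippocampus; each point is a gene, red where its limma adjusted p was under 0.05, and black bars mark list medians. The erythrocyte medians lie at 2.86, 2.86 and 2.75 and the cholesterol synthesis medians at -0.44, -0.32 and -0.53.

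Averaged over the 3 regions for each replicate number, the genes with the largest changes were again those of blood cells, acute phase and vessels on the rising side. S100a9, Alas2, Hbb-bt, S100a8, Lcn2, Retnlg and Vwf rose by log2 fold changes of 3.34 ± 0.46, 3.24 ± 0.40, 3.20 ± 0.35, 2.99 ± 0.39, 2.43 ± 0.11, 2.33 ± 0.26 and 2.26 ± 0.21. On the falling side stood Zbed6 (-1.26 ± 0.19), Gkn3 (-1.11 ± 0.15) and Lnpep (-1.09 ± 0.19), followed by Ptar1, Plcxd3, Lmbrd2, Lcor, Fzd3, Zfp871 and Arfgef3. An average fall need not be shared by all regions. For Lnpep, Ptar1, Plcxd3, Lmbrd2, Lcor, Fzd3 and Arfgef3, log2 fold changes were -2.25 to -1.52 in cerebellum but -0.11 to 0.02 in neocortex. In hippocampus Lnpep, Ptar1 and Fzd3 fell, by -1.02, -0.89 and -0.87. Of 14873 genes 1950 changed, 1139 upward and 811 downward. The count was 1267, 668, 939 and 4331 without LLC replicates 1 to 4, and 1168, 379, 465 and 812 without control replicates 14 to 17. Of the 20 genes with the largest changes all but Zfp871 kept their call in each of these fits.

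Separate tests in each region called many of the same genes. Among 13633 genes tested in all regions, 82 rose and 16 fell in all 3, against 0.246 and 0.0578 if the 3 sets of calls were independent. The rising genes included Lcn2, Lrg1, Vwf, Ly6a, Pecam1, Icam1, Ch25h, Cebpd, Fn1, Col4a1, Vegfa, Alas2, the 4 haemoglobin genes, S100a8, S100a9, Retnlg and Chil3. The falling genes included Cyp51, Idi1, Sc5d, Stard4, Gkn3, Itm2a, Hspd1 and Hspa4l. Neocortex and hippocampus shared 242 rising and 60 falling calls, against 20.8 and 4.49 for independent calls. Neocortex and cerebellum shared 114 and 29 (9.56 and 5.58), and cerebellum and hippocampus 89 and 41 (4.41 and 1.90). If the libraries of a number come from the same animal, part of this overlap may reflect the shared animals.

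Across genes, the log2 fold changes correlated with Pearson r = 0.800 between neocortex and hippocampus over 14152 genes, 0.656 between neocortex and cerebellum over 13783, and 0.663 between cerebellum and hippocampus over 13884. Spearman's rho was 0.728, 0.557 and 0.557. Genes are not independent replicates, so r was set against all 35 splits of the replicate numbers into 4 and 4: the other splits reached 0.751, 0.645 and 0.625, with medians of 0.356, 0.325 and 0.287. The real split was the highest in each case, a permutation share of 1 in 35 (0.0286, and 0.0286 adjusted over the 3 pairs).

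Direct tests of the difference between regions asked which genes responded unequally. Cerebellum and neocortex differed most clearly in Gda, the guanine deaminase gene (chromosome 19, 21391307 to 21473445), which rose in cerebellum (0.88 ± 0.11) and had a log2 fold change of -0.14 ± 0.04 in neocortex, a difference of 1.02 ± 0.09 (limma adjusted p = 1.90e-06). Klf10 fell in neocortex (-0.81 ± 0.09) and was at 0.19 ± 0.11 in cerebellum, a difference of 1.01 ± 0.14. Tnnc1, Hes5, Ier5, Npy, Tigd3, Gadd45b, Crip2 and Hid1 also had higher fold changes in cerebellum, by 0.30 to 1.19. Lower fold changes in cerebellum were found for Lnpep, Plcxd3, Ptar1, Lmbrd2, Arfgef3, Lcor, Stxbp5l, Fzd3 and Dgkh, with differences of -2.27 to -1.45, and for Etnppl, which rose in neocortex (1.79 ± 0.24) and was at 0.24 ± 0.09 in cerebellum. The intermediate filament gene Vim rose in neocortex (0.76 ± 0.11) and was at -0.21 ± 0.08 in cerebellum, a difference of -0.97 ± 0.15.

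The difference was called for 89 of 13783 genes, 11 with a higher and 78 with a lower fold change in cerebellum. Median-ratio scaling gave 20 and 63 and quantile normalization 28 and 64. The count was 49 without LLC replicate 2, 287 without LLC replicate 4, and 14, 11, 4 and 34 without control replicates 14 to 17. Gda and Klf10 kept their call in all 8 fits without a replicate. On simulated data 15.2% of the genes called in this comparison had not been changed, against a set rate of 5%.

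Hippocampus and cerebellum differed in 13 of 13884 genes. Vim, Samd5, Lacc1, Glis3, Shisa9, Lmo7 and Lcorl had higher fold changes in hippocampus, by 1.01, 0.89, 0.81, 0.79, 0.78, 0.70 and 0.58. Hes5, Gda, Npy, Ccdc3, Sh2b2 and Socs2 had lower ones, by -1.32, -1.06, -1.03, -0.80, -0.70 and -0.59. Npy, the gene of neuropeptide Y, fell in hippocampus (-0.36 ± 0.06) and rose in cerebellum (0.67 ± 0.15). The split was 6 up and 8 down with median-ratio scaling and 7 and 15 with quantile normalization. The count was 5, 3, 7 and 220 without LLC replicates 1 to 4 and 2, 1, 5 and 3 without control replicates 14 to 17; Gda kept its call throughout, and on simulated data 14.4% of called genes had not been changed.

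Between hippocampus and neocortex limma called 0 of 14152 genes, with 271 at an unadjusted p under 0.05 against 708 expected by chance. A count below chance means that the test may be too conservative, so 0 calls do not show that both regions responded alike. With the title number as a block the count was also 0. The genes with the smallest p, none of which passed (adjusted p = 1.00 for each), were Glis3, Fam43a, Zfp653, Npnt and Arhgap12 among those higher in hippocampus and Prss23, Nkain3, Drc1, Lgals3 and Chst14 among those lower. Without a filter on low values the test called 2 genes, and with weights for each library 0.

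**Figure D2:**
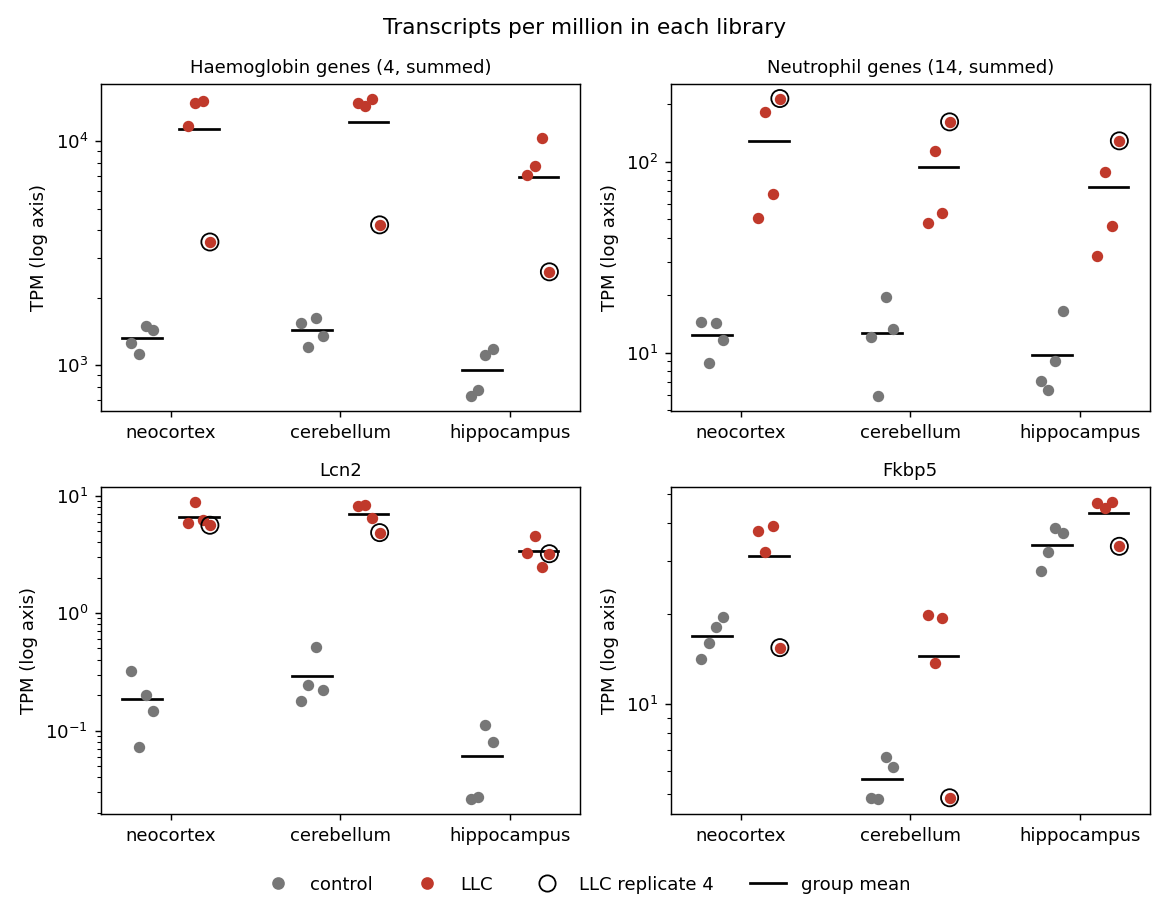
TPM (log axes) in each library of neocortex, cerebellum and hippocampus for the summed haemoglobin genes, the summed neutrophil genes, Lcn2 and Fkbp5, with bars at group means and LLC replicate 4 ringed; Fkbp5, a glucocorticoid target, was chosen after its values were seen. LLC replicate 4 has the lowest haemoglobin sum of the LLC libraries in each region (3545, 4228 and 2609 TPM) and the highest neutrophil sum (215, 162 and 129 TPM), and its Fkbp5 level (15.4, 4.87 and 33.5 TPM) lies within the control range.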

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

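All tests of explanations in this part, apart from the splits of the gene list tests, were chosen after the result they bear on was seen.

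Blood transcripts rose unevenly. Haemoglobin sums were 8.49, 8.53 and 7.31 times the control level in neocortex, cerebellum and hippocampus and neutrophil sums 10.4, 7.43 and 7.55 times, but the log2 ratio of neutrophil to haemoglobin TPM lay outside the range of the region's controls in 10 of 12 LLC libraries, 6 below and 4 above, against 4.80 by chance. The ratio spanned 3.81, 3.56 and 3.46 over the LLC libraries of the 3 regions and 0.541, 1.31 and 0.790 over the controls. These values go against more residual blood of unchanged make-up. Without LLC replicate 4, 3 of 3 LLC libraries in neocortex and 2 of 3 in cerebellum and in hippocampus still lay outside the control range. The spans do rest on that replicate: without it they were 1.51, 1.30 and 1.36, no wider than that of the controls in cerebellum. More residual blood of unchanged make-up therefore stays open (the need to hold without each replicate was set after a first reading had argued against it). That test replaced one of the mean ratio, which did not pass (adjusted exact permutation p = 0.971, the highest of the 3 regions), and was chosen from values already seen. The 12 libraries carry 4 title numbers, whose ratios agree across regions, so they are not 12 independent cases. Lymphocyte transcripts did not rise as the haemoglobin genes did: their sums were 0.890, 0.794 and 0.841 times the control level in neocortex, cerebellum and hippocampus. In hippocampus LLC replicate 4 did rise, to 14.2 TPM, above all controls, and without it the ratio was 0.367. Ighm, which is outside the sum, fell in neocortex from 50.4 to 22.2 TPM (limma adjusted p = 0.0452), but averaged 14.5 TPM in LLC and 8.70 TPM in control cerebellum and 16.4 and 17.5 TPM in hippocampus, where it did not pass (adjusted p = 0.543 and 0.648). Most of these values go against a like rise of all blood cells but leave it open. Controls held only 6.29 TPM in hippocampus and 5.40 TPM in cerebellum, below a floor of 20 TPM that was set after a first reading had argued against it. The 51.1 TPM of control neocortex came mostly from Trbc2 (34.4 TPM) and Cd4 (11.5 TPM), at 0.230 and 0.124 TPM in control cerebellum, so a high baseline of the tissue could hide a small share of blood. The tissue was not stated to be perfused in the labels used here, so blood left in the vessels, blood cells in the tissue and a changed blood cell count in LLC mice may all contribute.

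LLC replicate 4 stood apart from the other LLC libraries in all 3 regions, with the lowest haemoglobin sums, the highest neutrophil sums and glucocorticoid list scores of 0.00, 0.02 and 0.13, inside the control ranges. Of the 49 called lists, 14 had an LLC library that did not lie beyond all controls, and replicate 4 was among these in 12. A control animal labelled as LLC is argued against by its acute-phase genes, of which 68.8%, 68.4% and 81.2% lay above all 4 controls of the region. Sequencing depth is argued against by the TPM value of 1 read, inside the range of the other libraries in 3 of 3 regions. Its neutrophil score was the highest of the 4 LLC libraries in 3 of 3 regions, which may share 1 animal. That goes against a response weaker in every gene group. High neutrophil values are also a trait by which this replicate was picked out, so the score is not an independent test. Its erythrocyte, glucocorticoid and endothelial list scores were the lowest of the 4 in each region, and its acute-phase scores in neocortex and cerebellum. A weaker response outside the neutrophil genes therefore stays open. A later or earlier stage of tumour growth, another time of death and a different stress level may each fit and were not tested, since the labels give none of them.

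Genes falling in LLC cerebellum were long and poor in GC: fold changes over all cerebellar genes correlated with GC content (Spearman's rho across genes 0.374, against 0.169 in neocortex and 0.140 in hippocampus) and with length (-0.271). Once that trend was removed from each library, the falling genes kept 76.4% of their median log2 fold change (from -0.53, interquartile range -0.69 to -0.43, to -0.41, -0.62 to -0.26). This passed a bound of over 50% that replaced a bound of 75% after this value was seen. The genes had been chosen by their fall before the removal, so they would tend to keep part of it. The test therefore cannot decide whether the trend is the whole cause. Only 48 of the 176 genes with a value were still called. Of the 128 that were lost, 32 still met the limma cut-off of the main fit and were lost only to the stricter one that the adjustment set with fewer calls, and the other 96 all had a smaller change, 40 of them also a larger SE (median SE 0.10 before and 0.09 after). A part due to RNA quality or library preparation may remain. Without LLC replicate 1, whose length trend was the steepest of the cerebellar LLC libraries (-0.386), 90.7% of the median was kept and all 186 genes were called. Its GC trend (0.293) was less steep than that of LLC replicate 4 (0.396), so this does not test the GC trend. Other replicates mattered more: falling calls numbered 640, 6, 15 and 950 without LLC replicates 1 to 4. Without control replicates 14 to 17 they numbered 5, 1, 0 and 22. The library of LLC replicate 1 also stood apart in make-up, with a mean log2 difference from controls of -0.84 for the cerebellum markers (other LLC libraries -0.07 to 0.02) and 0.40 for the myelin genes (-0.51, -0.47 and -0.02), and why it did was not tested.

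In 51 of 586 groups of 4 libraries, 1 library lay apart from the others (the gap to its nearest neighbour, divided by the range, exceeded Dixon's critical value; these ratios stand in parentheses below), against 29.3 by chance; 36 were LLC groups, 33 of them with replicate 4 apart, and 15 were control groups. The groups covered library measures, named genes, Fkbp5, the blood sums and the lists called in the region. The same items were searched in LLC and control groups, and the control groups alone show no clear excess over chance. Many groups overlap, such as the haemoglobin sum, its single genes and the erythrocyte list, so they are not independent cases. Lists that were not called, such as the cerebellum markers and choroid plexus genes, were not searched. In neocortex, LLC replicate 4 lay apart for Alas2 (0.878), Klk6 (0.941), Myoc (0.917), Hes5 (0.910), Tst (0.873), Gjb6 (0.900), Ighm (0.906), Vegfa (0.892), Cryab (0.885), Cyp51 (0.862), Hmgcs1 (0.869), Sqle (0.846), the glucocorticoid list (0.858), the erythrocyte list (0.834) and the cholesterol list (0.852), and LLC replicate 2 for Lcn2 (0.835). In cerebellum, LLC replicate 4 did so for the haemoglobin sum (0.899), Hbb-bt (0.929), Hba-a1 (0.941), Hba-a2 (0.878), Fabp7 (0.867), Gabra2 (0.948), Vegfa (0.885), the glucocorticoid list (0.845) and the erythrocyte list (0.939). In hippocampus it did so for Vim (0.859), Cck (0.870), Kcnj8 (0.859), Vegfa (0.935), Cdkn1a (0.945), Fkbp5 (0.845), the lymphocyte sum (0.870), the glucocorticoid list (0.892) and the hypoxia list (0.843), LLC replicate 3 for Trh (0.861), and LLC replicate 2 for the basement membrane list (0.892). Among neocortex controls it was replicate 16 for Aldoc (0.843), replicate 15 for Gria1 (0.942) and replicate 17 for Ly6a (0.931). Among cerebellar controls it was replicate 14 for the number of genes at 1 TPM or more (0.851), Gpx3 (0.857) and Ankrd37 (0.934). Among hippocampal controls it was replicate 17 for Avp (0.875), Zbed6 (0.848) and Chil3 (0.840), replicate 16 for Fzd3 (0.901), Cebpd (0.902) and Cox5a (0.990), replicate 15 for Camk2b (0.852) and Hmgcs1 (0.949) and replicate 14 for the hypoxia list (0.916).

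Effects differed between cerebellum and neocortex for 89 genes by the test of the difference itself. Cerebellum minus neocortex, the log2 differences were 1.19 for Tnnc1, 1.09 for Hes5, 1.02 for Gda, 1.01 for Klf10, 0.88 for Ier5, 0.71 for Npy, 0.62 for Tigd3, 0.60 for Gadd45b, 0.51 for Crip2, 0.30 for Hid1, -2.27 for Lnpep, -1.99 for Plcxd3, -1.85 for Ptar1, -1.77 for Lmbrd2, -1.76 for Arfgef3, -1.74 for Lcor, -1.55 for Etnppl, -1.48 for Stxbp5l, -1.46 for Fzd3 and -1.45 for Dgkh. Effects differed between hippocampus and cerebellum for 13 genes, and hippocampus minus cerebellum the differences were 1.01 for Vim, 0.89 for Samd5, 0.81 for Lacc1, 0.79 for Glis3, 0.78 for Shisa9, 0.70 for Lmo7, 0.58 for Lcorl, -1.32 for Hes5, -1.06 for Gda, -1.03 for Npy, -0.80 for Ccdc3, -0.70 for Sh2b2 and -0.59 for Socs2.

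The 8 replicate numbers split into 4 and 4 in 35 ways. For neocortex, cerebellum, hippocampus and the region average only the real split, 1 of 35, gave as many genes (1237, 366, 529 and 1950). The highest of the others gave 0, 0, 1 and 1, which argues against chance. The same held for cerebellum against neocortex (89, other splits 0). For hippocampus against cerebellum the real split was again the only 1 of 35 with as many (13), but another gave 7, so chance is argued against only narrowly and single genes stay uncertain. A share of 1 in 35 is the smallest this design can give, and it is not adjusted over the comparisons, so it excludes chance for none of them. For hippocampus against neocortex the real split gave 0 and all 35 splits gave as many, up to 41 in a split that set LLC replicates 1 and 3 with control replicates 15 and 16, a number that may point to a structure of the samples, which was not tested. For the camera list tests 7 of 35 splits gave as many as the real 49, with 53 as the highest, so for their number chance cannot be excluded. With fry the real split gave 23 and the others 0, and of the 49 called lists 15 had their smallest camera p and 32 their smallest fry p in the real split. A camera p as small came up most often for the mural (20 of 35 splits), ribosomal protein (17) and complement (14) lists in cerebellum, the respiratory chain (15) and unfolded protein response (11) lists in hippocampus, and the microglial (12) and immediate early (11) lists in neocortex. For the glucocorticoid list it came up in 5, 7 and 4 of 35 splits in neocortex, cerebellum and hippocampus. For the hypoxia list it did so in 4, 5 and 6, and for cholesterol synthesis in cerebellum in 8.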

How the results depend on the processing

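The removal of GC and length trends and the weights per region were chosen after seeing the data. The cause of the differences below was not tested, except that fewer libraries or genes enter some fits. Without a filter, which adds low genes to the adjustment, 577 neocortex, 71 cerebellum, 220 hippocampus and 1088 average genes passed, and 2 for hippocampus against neocortex. Library weights gave 4337, 5769, 1180 and 5308, and 2052 for cerebellum against neocortex and 595 for hippocampus against cerebellum. All 24 libraries in 1 fit gave 784 in neocortex and 3012 in cerebellum. In cerebellum median-ratio scaling gave 742, quantile normalization 825 and GC and length removal 154. Hippocampus against cerebellum gave 3 with the filter at 5 TPM, 22 with quantile normalization and 6 with weights per region. Gene list tests gave 0 calls with an estimated correlation and 23 with fry.

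As a replicate block, the description number (1 to 4 in both groups) gave 641 in neocortex, 724 in cerebellum and 179 in hippocampus, and the title number (LLC 1 to 4, control 14 to 17), which blocks only across regions, 205 for cerebellum against neocortex and 40 for hippocampus against cerebellum; the description number ended 1 list call, nuclear respiratory chain genes in hippocampus (adjusted p = 0.0529). By title number 18 of 24 pairs of libraries correlated best with their own number (8 of 8 for neocortex and cerebellum, 7 for cerebellum and hippocampus, 3 for neocortex and hippocampus), a hint from the data at shared animals. Only 16 of the 24 correlated above 0.1, so no result rests on the block, though the region average and the splits keep the libraries of a title number together; by description number 5 of 12 pairs did so and 3 were best with their own.

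Leaving out 1 replicate, the counts ranged from 187 to 3834 in neocortex, 6 to 1570 in cerebellum, 57 to 1667 in hippocampus, 379 to 4331 for the average, 4 to 287 for cerebellum against neocortex and 1 to 220 for hippocampus against cerebellum, each highest without LLC replicate 4. The correlation of fold changes ranged from 0.573 to 0.674 for neocortex and cerebellum, 0.708 to 0.825 for neocortex and hippocampus and 0.599 to 0.674 for cerebellum and hippocampus. Of 6851 values of 391 named gene results, 4992 kept direction and call, 1858 kept direction without passing, and 1 reversed, mt-Nd4l in the average with quantile normalization (0.0212). Read depth limits low genes by an amount that TPM values do not show.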

Other observations

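The biology in this part was picked after the values were seen, and no explanation is tested in it. Interferon-responsive genes were not called as a list in any region, with medians of -0.11, -0.09, -0.05 in neocortex, cerebellum and hippocampus and camera adjusted p = 0.0760, 0.917 and 0.714. Of its members, Ifitm3 rose in cerebellum (0.43 ± 0.09, limma adjusted p = 0.0399). In the region average Ifitm3 (0.47 ± 0.05) and Rsad2 (0.38 ± 0.11) rose and Gbp3 fell (-0.52 ± 0.10). Antigen presentation genes were not called as a list either (medians -0.01, -0.09 and 0.05, camera adjusted p = 0.822, 0.168 and 0.889). The clock genes were not called as a list (adjusted p = 0.955, 0.928 and 0.276), but Dbp, a clock-controlled transcription factor, fell in neocortex (-0.40 ± 0.08) and cerebellum (-0.67 ± 0.12) and stood at -0.24 ± 0.12 in hippocampus, where it did not pass. Npas2, a partner of the clock, rose in neocortex (0.29 ± 0.06).

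Beside Avp, hippocampus of LLC mice held more Trh, the gene of thyrotropin-releasing hormone, a hypothalamic marker (from 0.862 ± 0.217 to 2.13 ± 0.761 TPM; limma adjusted p = 0.0447), with LLC replicate 3 at 3.26 TPM. Among the LLC libraries Avp was lowest in replicate 3, at 6.09 TPM. The glucocorticoid targets Fkbp5 and Sgk1 did not pass in any region: log2 fold changes were 0.77 ± 0.25, 1.07 ± 0.35 and 0.34 ± 0.13 for Fkbp5 and 1.06 ± 0.34, 0.99 ± 0.32 and 0.92 ± 0.28 for Sgk1, with LLC replicate 4 at 34.1, 44.7 and 40.3 TPM of Sgk1, inside the control ranges.

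Some lists that were not called had a median, mean and test that differed in sign. Examples are the choroid plexus genes in neocortex (median 0.04, mean -0.01, test downward, adjusted p = 0.752), the astrocyte genes in neocortex (median -0.03, mean 0.03, test upward, adjusted p = 0.849) and the lipid use genes in cerebellum (median -0.07, mean 0.10, test upward, adjusted p = 0.909).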
